A study of Caenorhabditis elegans with 2 samples.

How the data were processed

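SNPC-4 tagged with GFP was profiled by ChIP-seq in 2 biological replicates of whole young adult hermaphrodites, per the labels, and both formed the only group. The description names an anti-GFP antibody, while the antibody entry of the labels reads snpc-4, and the description was followed here. The authors deposited narrowPeak lists without headers in the ce10 and ce11 builds: candidate regions (peaks and background prepared as IDR input) for each replicate and for the pooled replicates, and the list of pooled peaks past the IDR threshold. Per the text listing deposited with the samples, the lists were derived from alignments of the replicates and of a control. The peak caller, the aligner and their versions are not given in the sources used here. Each candidate list held exactly 30000 regions, so its lower end is a rank and not a fixed level of enrichment.

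The signal value deposited for each region is the authors' measure of peak strength, and its scale is not given in the sources used here. It was used to rank and describe peaks within 1 list and was not compared in level between lists. The −log10 q-value deposited for each region took the same, highest value in all 4675 IDR peaks, so it was not used for ranking. The summit is the deposited offset from the start of the region, converted here to a coordinate counted from 1. The deposited lists give no read counts, so depth per sample is unknown and no interval that needs it is given. Intervals on shares of genes or peaks are exact binomial at 95% and cover counting error only.

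Gene positions and biotypes came from the Ensembl release 115 annotation of WBcel235, the assembly of ce11, and the sequence from the RefSeq version of the same assembly. The last regions on chromosomes V and X ended exactly at the chromosome ends of 20924180 and 17718942 bp. Gene symbols printed are those of RefSeq, which covered 99.9% of 46926 genes. The SL RNA class was counted with Ensembl names (30 genes). RefSeq symbols place 1 further gene, the pseudogene sls-2.19, in it (31 genes, odds ratio 38.1). Both counts were seen before the first was kept as the main one, since it follows the definition fixed before the data were examined.

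A summit belonged to a gene class if it lay within 300 bp of a 5' end of that class, and could belong to several. IDR peaks were compared with the 25325 pooled candidates outside the IDR list by Fisher's exact test (two-sided), over 10 gene classes, within chromosome IV for the piRNA domains, and for the motif CTGTTTCA within 100 bp of the summit on either strand. Genes in 9 lists of protein-coding genes (piRNA pathway, ribosomal proteins, histones, germ granule and germline, vitellogenins, collagens, muscle, neuronal, RNA polymerase and general transcription factors) were compared with all other protein-coding genes that had a candidate at the 5' end. Median signals were compared by permutation with 100000 resamples for the 9 classes with at least 10 peaks. Benjamini-Hochberg adjustment was made within each family. Peaks are not biological replicates, so these p-values describe the spread over regions and not over animals. Regions can also overlap: the 30000 pooled candidates merged into 19867 regions and the 4675 IDR peaks into 4239. Except where overlapping regions were merged, Fisher's exact test took each candidate as independent. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.

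The gene classes, lists, domains, motif, tests and most alternatives were fixed before the data were examined. The genes named were the 3 at the highest peaks of each of 7 non-coding classes, the 6 protein-coding genes at the highest peaks with no 5' end of those classes within 500 bp, rpr-1, mrpr-1, snpc-4, prde-1, tofu-4, tofu-5 and prg-1 whatever their values, and up to 2 per list. Neighbouring genes closer to the same summits were added after the values were seen. Alternatives were windows of 150 and 500 bp, the 50% of IDR peaks with the highest signal, each replicate list alone with its 4675 strongest regions, merging of overlapping regions, 10000 rotations of the pass labels along each chromosome, 1000 random placements, the nearest 5' end only, ce10 lists, domains set by 100 kb bins with at least 20 piRNA genes, motif distances of 50 and 200 bp, the reversed motif, other overlap rules, and lists without genes near small RNA genes. Leaving out the mitochondrial genome and using RefSeq symbols were added after the data were examined.

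The tests were tested on simulated labels over the 30000 candidates. With random labels, Fisher's exact test at tRNA genes gave p under 0.05 in 3.0% of 200 simulations, and a simulated odds ratio of 4 was recovered with a median of 4.02. With labels clustered along the chromosomes and unrelated to piRNA genes, Fisher's exact test gave p under 0.05 in 75.0% of 100 simulations and rotation in 2.0%. The strength of that clustering was a setting of the simulation and was not matched to the IDR labels. Fisher's p-values are therefore too small where labels cluster in this way, by an amount not measured for the IDR labels. Rotation was run for the gene classes, the domains and the motif CTGTTTCA, and not for the signal medians, the gene lists or TGTCGG. The median test gave p under 0.05 in 2.0% of 100 simulations without a change and in 100.0% where the signal of 100 peaks was doubled.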

Results

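Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic sites of SNPC-4 in whole *Caenorhabditis elegans*. SNPC-4 is the worm homologue of the largest subunit of SNAPc, the complex that binds promoters of small nuclear RNA genes. The strain, YL487, carried a transgene for SNPC-4 with a C-terminal GFP-FLAG tag, and an anti-GFP antibody was used. Hermaphrodite young adults were collected 60 h after release from starvation arrest as first-stage larvae. The labels give 1 group with 2 biological replicates, so the comparisons below are between genomic regions and not between conditions. The values are peak lists in the ce11 genome build. A list of 30000 candidate regions was given for each replicate and for both replicates pooled, and 4675 of the pooled candidates formed the list that passed the irreproducible discovery rate (IDR) threshold, called IDR peaks here. The IDR peaks had a median width of 464 bp. Read depth is unknown from these lists, and the signal value of a peak is the authors' own measure of peak strength.

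The replicates shared most of their strongest sites. Of the 4675 strongest regions of replicate 1, 77.0% had their summit inside such a region of replicate 2, and 77.9% the other way round. The pooled signal that set the IDR peaks apart came from both replicates, so their own shares are set in part by it. Of the 4675 IDR peaks, 97.8% had a summit inside a candidate region of each replicate, against 60.6% of the other pooled candidates. In the 4675 strongest regions of both replicates lay 74.8% of the IDR peaks and 2.63% of the other candidates. The peak of highest signal in the pooled list, at the snoRNA gene ZK994.7, was also ranked 1 in replicate 1 and in replicate 2. Across the 4574 IDR peaks found in both replicates, Spearman's rho between the signal values was 0.834; this is a correlation across peaks, which are not independent replicates. The IDR peaks were exactly the pooled candidates of highest signal, with a lowest signal of 87.3, so the threshold acted as a limit on rank. No peak was kept or dropped for its own agreement between replicates, and passing IDR below means a higher pooled signal. Requiring regions to overlap by 50% of each lowered the shared part to 79.0% and 59.1%.

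SNPC-4 peaks lay at snRNA, SL RNA, tRNA and snoRNA genes far more often than the remaining candidates did. An IDR summit was found within 300 bp of the 5' end of 75 of 99 snRNA genes (75.8%, exact 95% interval 66.1 to 83.8), 393 of 634 tRNA genes (62.0%, 58.1 to 65.8), 18 of 30 spliced leader (SL) RNA genes (60.0%, 40.6 to 77.3) and 111 of 346 snoRNA genes (32.1%, 27.2 to 37.3). The tRNA count includes mitochondrial genes, and among nuclear tRNA genes it was 379 of 612 (61.9%). The SL RNAs donate the short leader that is trans-spliced onto many worm mRNAs. Together these 4 classes accounted for 13.0% of the IDR peaks and 0.920% of the other candidates. The 4 strongest sites were of this kind: ZK994.7 (snoRNA) ranked 1, sls-2.4 (SL RNA) ranked 2, Y53F4B.47 (snoRNA) ranked 3 and sls-2.1 (SL RNA) ranked 4.

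By class, with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment over 10 classes, the odds ratio for passing IDR was 41.4 (95% interval 22.7 to 75.7, adjusted p = 6.6e-59) at snRNA genes and 36.3 (10.8 to 122, adjusted p = 1.3e-13) at SL RNA genes, where replicate 2 alone gave 114. By the same exact test it was 18.9 (15.3 to 23.2, adjusted p = 2.0e-207) at tRNA genes and 6.56 (5.00 to 8.61, adjusted p = 1.8e-38) at snoRNA genes. The sizes depended on the setting: a 150 bp window gave 136 at snRNA, 51 at tRNA and 12.8 at snoRNA genes, and 500 bp gave 19 at SL RNA genes. In the 50% of IDR peaks with the highest signal they were 73.8 at snRNA, 72.9 at SL RNA, 30.4 at tRNA and 11.7 at snoRNA genes, and merged regions gave 36.7 at tRNA genes. In the exact test smaller enrichments were found at other non-coding RNA genes (652 peaks, odds ratio 3.48, 3.15 to 3.86, adjusted p = 1.6e-111, and 2.30 by the nearest 5' end only), miRNA genes (30 peaks, 2.63, 1.70 to 4.07, adjusted p = 9.2e-05) and protein-coding genes (1116 peaks, 1.77, 1.64 to 1.91, adjusted p = 4.1e-46). Genes for rRNA (5 peaks, odds ratio 2.71, 0.926 to 7.93, adjusted p = 0.088) and pseudogenes (47 peaks, 1.04, 0.757 to 1.42, adjusted p = 0.81) did not pass the exact test, although the rRNA odds ratio was 6.51 and passed without replicate 1, and was 1.63 without the mitochondrial genome. Neither did piRNA genes pass the exact test, with 890 peaks (19% of the IDR peaks against 18.8% of the other candidates, odds ratio 1.01, 0.936 to 1.1, adjusted p = 0.81). The piRNA value depended on which peaks were counted: among the 50% of IDR peaks with the highest signal the odds ratio was 0.448. It was 1.17 without replicate 1 and 1.24 with overlapping regions merged, and passed in both. Summits placed at random on the same chromosomes gave a 2.22-fold excess of observed peaks. With the labels rotated along each chromosome, a permutation that keeps their clustering, the piRNA count was 1.04-fold its mean and did not pass. Under the same rotation the peak count was 5.87-fold the mean at snRNA, 6.10-fold at SL RNA, 3.85-fold at tRNA and 3.60-fold at snoRNA genes, each past the threshold. As ratios of counts without rotation these were 5.66, 5.58, 4.89 and 3.48.

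**Figure D1:**
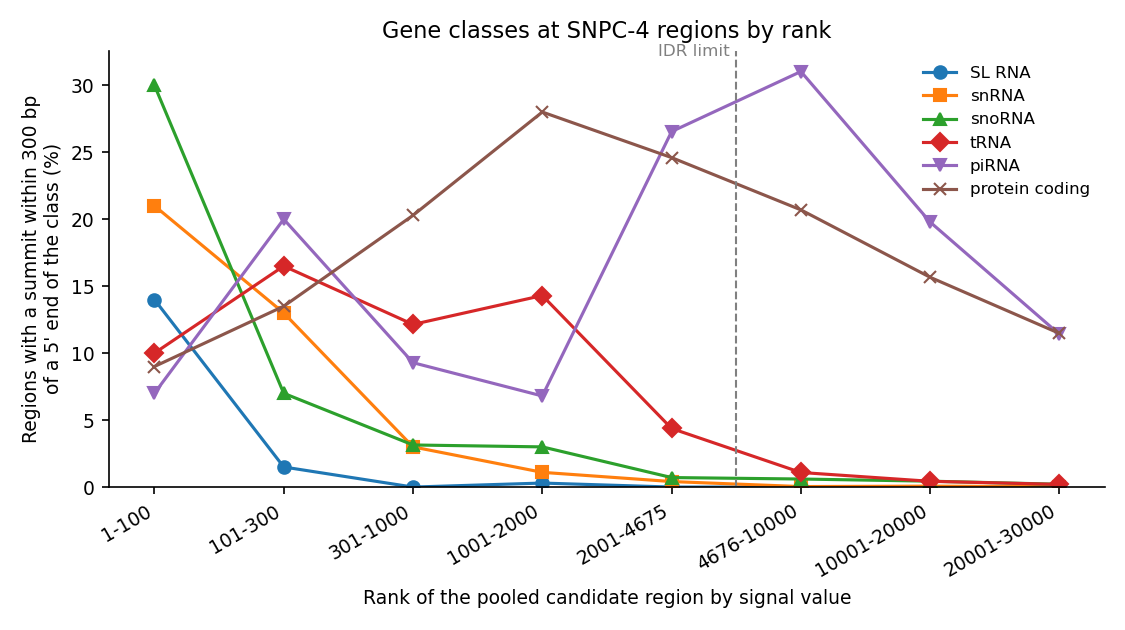
Percent of pooled candidate regions (y axis) whose summit lay within 300 bp of the 5' end of a gene of each class, in bins of rank by signal value (x axis, rank 1 is the highest); the dashed line marks the IDR limit and a region can count for several classes. Among the 100 strongest regions 30% lay at snoRNA, 21% at snRNA, 14% at SL RNA and 10% at tRNA genes, and 45% at other non-coding RNA genes, which are not drawn, while piRNA genes reached 31.0% just after the IDR limit.

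The named sites showed where the strongest peaks sat. All coordinates are in ce11. The SL RNA gene sls-2.4 (I, 4172206 to 4172315, plus strand) had its summit at 4172160, 46 bp upstream of the 5' end, with a signal of 31586. At sls-2.1 (II, 5844865 to 5844974) the summit lay 47 bp upstream (signal 31242), and at sls-2.2 (II, 5543598 to 5543707) 41 bp upstream (signal 22867). The highest snRNA peaks were at W05B2.8 (III, 10989679 to 10989780, 28 bp upstream, signal 22264), sup-6 (II, 12944803 to 12944967, 19 bp upstream, signal 17455) and C52E4.8 (V, 11980118 to 11980261, 58 bp upstream, signal 14000). The snoRNA genes were led by ZK994.7 (V, 8500579 to 8500645, 35 bp upstream, signal 34251), followed by Y53F4B.47 (II, 15025814 to 15025893, 76 bp upstream, signal 31541) and Y37E3.20 (I, 2085037 to 2085155, 56 bp upstream, signal 22988). The gene rpr-1, which encodes the RNA of RNase P (I, 13463955 to 13464207), had a peak 21 bp upstream that ranked 6 with a signal of 22917. The gene mrpr-1, for the RNA of RNase MRP (II, 7200233 to 7200418), had one 26 bp upstream that ranked 40 with a signal of 9292. Among miRNA genes the highest peaks were at mir-2214 (54 bp upstream, rank 27), mir-8196.1 (46 bp upstream, rank 59) and mir-8196.2 (42 bp upstream, rank 84).

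Several of the top-ranked assignments shared a peak with a neighbouring gene. The non-coding genes R12E2.18 and Y37E3.29 were assigned the same peaks as sls-2.4 and Y37E3.20, and the summit at sup-6 lay 2 bp from the 5' end of the non-coding gene F58G1.11. The strongest tRNA assignment, M01E5.t1 (rank 23, 75 bp upstream), was closer to the SL RNA gene sls-2.9 (57 bp). It was followed by C27A2.t1 (rank 31, 17 bp upstream) and by a mitochondrial tRNA gene, WBGene00014464 (rank 51). The summit of the latter lay 263 bp downstream of the 5' end and was closer to the protein-coding gene WBGene00000829 (206 bp). The strongest peak assigned to a piRNA gene, 21ur-7591 (IV, 14327393 to 14327413, rank 15), lay 240 bp from that gene and 52 bp from the snoRNA gene Y67A10A.14. Likewise the peak at 21ur-14704 (rank 63) lay 261 bp upstream of it and 41 bp from the snRNA gene sup-39. Only at 21ur-1009 (rank 56, 28 bp downstream) was the piRNA gene the closest annotated 5' end among these 3.

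Summits at SL RNA, snRNA and snoRNA genes lay mostly upstream of the gene start, at similar distances. With negative values upstream, the median offset was -40.5 bp at SL RNA, -30 bp at snRNA and -43 bp at snoRNA genes, and 90.0% (exact 95% interval 68.3 to 98.8), 73.3% (63.0 to 82.1) and 87.8% (80.4 to 93.2) of their summits were upstream. At tRNA genes the median was 11 bp, inside the gene, and 30.7% (26.1 to 35.5) of 388 summits were upstream. At protein-coding genes the median was -128 bp with 81.2% (78.8 to 83.4) of 1116 summits upstream, and at piRNA genes it was -12 bp with 55.2% (51.8 to 58.5) upstream. The median was -85 bp at miRNA genes and 56.5 bp at other non-coding RNA genes. Differences between classes were not tested, and these offsets were examined without a plan fixed before.

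**Figure D2:**
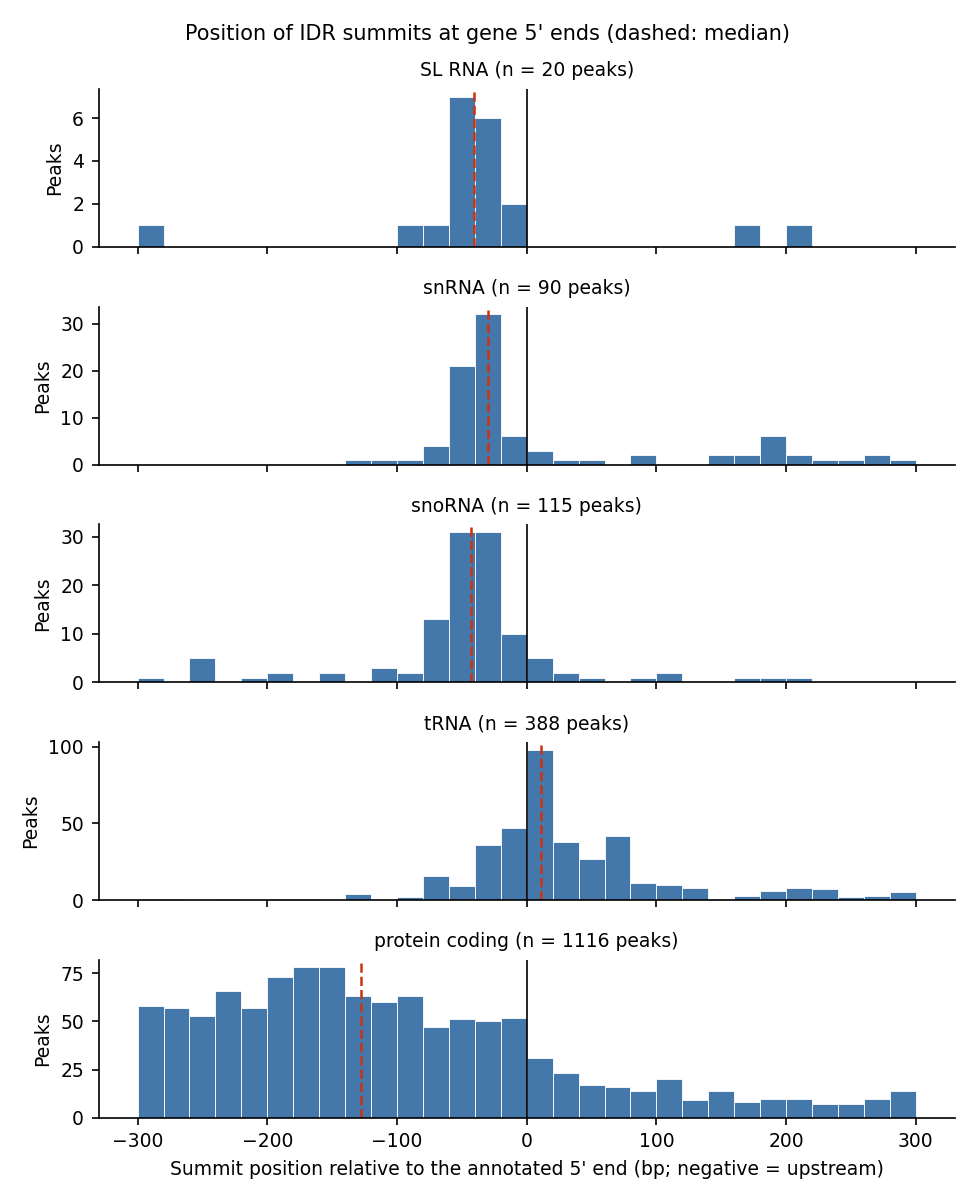
Number of IDR summits (y axis) by position relative to the nearest annotated 5' end of the class (x axis, bp, negative is upstream) in 20 bp bins; the solid line marks the 5' end and the dashed line the median. Summits at 20 SL RNA, 90 snRNA and 115 snoRNA peaks cluster upstream of the start, those at 388 tRNA peaks around it, and those at 1116 protein-coding peaks are spread upstream.

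Among the IDR peaks, strength also differed by class. The IDR list is itself a cut on this signal, so the comparison is not independent of the odds ratios above. The median signal was 4547 at SL RNA genes against 164 at the other IDR peaks, 1277 against 162 at snRNA genes, 420 against 162 at snoRNA genes, 274 against 158 at tRNA genes and 234 against 157 at other non-coding RNA genes. Peaks at piRNA genes were weaker than the other peaks (120 against 184). Each of these 6 differences gave adjusted p = 1.5e-05 in a two-sided permutation test of medians with 100000 resamples, where the unadjusted p of each, 1e-05, was the smallest these permutations can give, adjusted over 9 classes. The ratio of medians had the same direction in each replicate, for example 8.73 and 8.90 at snRNA genes, 31.7 and 52.2 at SL RNA genes and 0.639 and 0.686 at piRNA genes in replicates 1 and 2. Peaks at miRNA genes (147 against 165, adjusted p = 0.58), pseudogenes (180 against 165, adjusted p = 0.58) and protein-coding genes (165 against 164, adjusted p = 0.82) did not pass the permutation test.

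On the nuclear chromosomes, SNPC-4 peaks were denser in the 2 domains of chromosome IV that hold most piRNA genes than elsewhere. The left domain runs from 4.5 to 7 Mb, and the right one spans 3.7 Mb from position 13500001. The domains make up 6.18% of the genome and held 1406 IDR peaks, 30.1% of the total, with 27.6% of all 30000 candidates and 92.5% of 15363 annotated piRNA genes. The density was 227 peaks per Mb in the domains, 42.9 on the rest of chromosome IV and 33.5 on the other nuclear chromosomes. Per 500 kb, the left domain held 37 to 54 IDR peaks. In the right domain, the 5 bins from position 14000001 to 16500000 held 149 to 195, and the bins on either side of them 102 and 128. The last bin of the chromosome, only partly in the domain, held 73. Within chromosome IV, 74.4% of 1890 IDR peaks and 64.6% of the other candidates lay in the domains (odds ratio 1.59, 1.43 to 1.78, Fisher's exact test p = 3.5e-17). As a ratio of counts this was 1.13-fold, and of the same size but not past the threshold in the permutation that rotated the labels along the chromosome (p = 0.13, against 8.1e-29 to 0.00052 under the other alternatives). The domains differed in direction: 8.57% of 2823 candidates passed IDR in the left domain and 21.3% of 5464 in the right one, against 11.4% on the rest of the chromosome. With the other domain left out, the odds ratios were 0.731 (0.621 to 0.860) and 2.11 (1.88 to 2.37) by Fisher's exact test. The rotation compared each domain with all of chromosome IV, the other domain included. In this permutation test the counts were 0.569-fold and 1.41-fold the rotation mean (unadjusted permutation p = 0.049 and 0.042). The rotation therefore did not test either domain against the rest of the chromosome alone. The domains were taken separately after the data were examined.

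**Figure D3:**
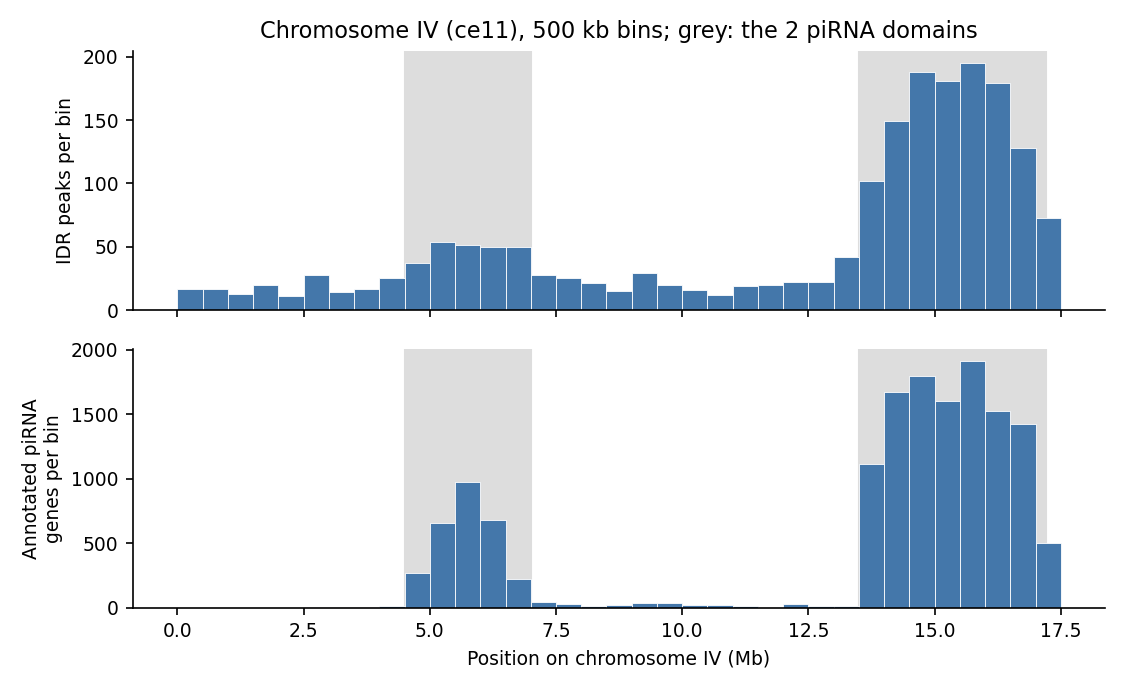
IDR peaks (upper panel) and annotated piRNA genes (lower panel) per 500 kb bin along chromosome IV in ce11 (x axis, Mb); grey areas are the 2 piRNA domains and the last bin ends at the chromosome end. Peaks reach 195 per bin in the right domain, where piRNA genes reach 1915 per bin, and 54 per bin in the left domain.

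The core of the motif upstream of piRNA genes, CTGTTTCA, was common in the domains but no more so under IDR peaks. It occurred within 100 bp of 25.1% of domain IDR summits and 23.8% of the other domain candidates (odds ratio 1.07, 0.938 to 1.22, Fisher's exact test p = 0.32), and at 14.4% of 20000 random domain positions. The reversed sequence ACTTTGTC occurred at 0.569% of the domain IDR summits. Outside the domains the motif was found at 0.765% of IDR summits and 1.22% of the other candidates (odds ratio 0.624, 0.412 to 0.945, exact p = 0.026), a difference not past the threshold with rotated labels. The reversed sequence had a similar ratio there (0.459% against 0.721%, odds ratio 0.635, 0.372 to 1.08), without passing the test, so a deficit specific to the motif was not shown. The value in the domains turned around for the 50% of IDR peaks with the highest signal: 7.82% carried the motif (odds ratio 0.271, 0.198 to 0.370). The pooled share thus joined unlike parts. In a split made after the data were examined, the motif was at 5.61% of 499 domain IDR peaks ranked 1 to 2000. It was at 35.8% of the 907 ranked after 2000, and at 32.9% of the domain candidates ranked 4676 to 10000, just outside the IDR list.

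The share of regions with the motif changed with rank. In the domains it was found at 0% of the 111 regions ranked 1 to 300, at 12.1% of those ranked 1001 to 2000 and at 38.1% of those ranked 3001 to 4675, before it declined to 16.3% at ranks 20001 to 30000. The sequence TGTCGG ran the other way, from 38.7% of domain regions ranked 1 to 300 to 8.79% at ranks 3001 to 4675. Elsewhere in the genome TGTCGG fell from 58.2% to 17.1% over the same ranks, with 8.99% and 4.34% for the reversed sequence GGCTGT. TGTCGG was taken after the data were examined. It was the most frequent of the 6-base sequences counted in the 100 bp upstream of 115 SL RNA, snRNA and snoRNA genes with strong peaks (61 of the 115). Its frequency at those classes is therefore not independent evidence, and part of its fall with rank was set by that choice. With regions at those classes left out, TGTCGG fell from 32.3% to 8.81% in the domains and from 57.8% to 17.1% elsewhere over the same ranks, and GGCTGT from 10.8% to 3.46% and from 8.82% to 4.11%.

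**Figure D4:**
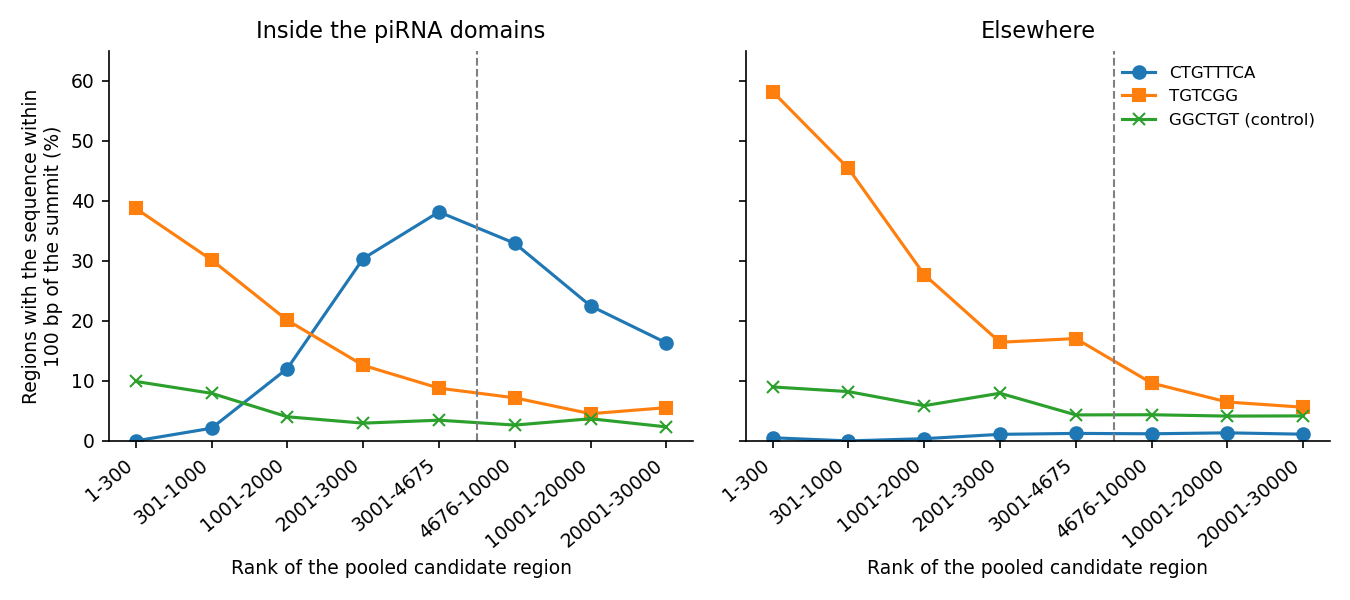
Percent of candidate regions (y axis) with CTGTTTCA, TGTCGG or the control GGCTGT within 100 bp of the summit on either strand, by rank of the pooled region (x axis), inside the piRNA domains (left) and elsewhere (right); the dashed line marks the IDR limit. In the domains CTGTTTCA rises from 0% to 38.1% of regions up to the IDR limit while TGTCGG, chosen at genes with strong peaks, falls from 38.7% to 8.79%.

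Among protein-coding genes, peaks were enriched at ribosomal protein genes. This list was chosen as one whose promoters are bound in many worm ChIP-seq sets, and whether the enrichment is particular to SNPC-4 was not tested. Of the 44 ribosomal protein genes with a candidate region within 300 bp of the 5' end, 32 (72.7%) had an IDR peak there, against 29.6% of 4185 other protein-coding genes (odds ratio 6.33, 3.25 to 12.3, Fisher's exact test, p = 5.1e-08 adjusted over the 9 lists alone). The highest were rpl-29 (IV, 13882225 to 13882618, 265 bp upstream, signal 1905, rank 178) and rpl-18A (IV, 4749123 to 4749778, 288 bp upstream, signal 1625, rank 211), although the latter summit was nearer to Y17G9B.5 (174 bp). Both rpl genes lie in the piRNA domains, where peaks were dense in general. The size of the enrichment depended on the window: the odds ratio was 2.20 and no longer past the threshold with 150 bp, 22.3 with 500 bp, and 16.6 with overlapping regions merged.

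The other lists did not pass. By the same exact test, a peak was found at 11 of 23 genes for RNA polymerase subunits and general transcription factors (odds ratio 2.14, adjusted p = 0.30), led by rpb-11 (124 bp upstream, rank 572) and rpb-12 (286 bp upstream, rank 913). Among histone genes 8 of 16 had one (odds ratio 2.33, exact test, adjusted p = 0.30), including the divergent pair his-67 and his-68, which share a peak (rank 712). In the piRNA pathway list 4 of 7 had one (odds ratio 3.11, exact test, adjusted p = 0.38). The snpc-4 gene itself (I, 8962322 to 8966129) had a peak 231 bp upstream (signal 694, rank 491), and snpc-3.1 had one 236 bp upstream (rank 1016), 219 bp from the neighbouring gene puf-7. The piRNA biogenesis gene prde-1 had only a candidate below the IDR limit (signal 81.1, rank 5064), and tofu-4, tofu-5 and prg-1 had no candidate within 300 bp. Collagen genes had peaks at 3 of 21 (odds ratio 0.386, exact test, adjusted p = 0.34), among them col-85 and col-137 with summits inside the gene, nearer to the 5' ends of the non-coding gene T21B4.18 (36 bp) and the piRNA gene 21ur-42 (126 bp). Germ granule and germline genes had 1 of 9 (odds ratio 0.290, exact test, adjusted p = 0.42), which was the germ granule gene pgl-1 (rank 4271). Vitellogenin genes had 0 of 4 (exact test, adjusted p = 0.42), muscle genes 0 of 2 (adjusted p = 1), and no neuronal gene of the list had a candidate. The intervals were wide, for example 0.874 to 6.23 for histone genes, and only histone genes passed under an alternative (4.85 in the 50% of IDR peaks with the highest signal). Without replicate 1 the odds ratio was 0.233 for collagen, 2.06 for piRNA pathway and 0.644 for vitellogenin genes, and without replicate 2 it was 1.39 for RNA polymerase and general transcription factor genes and 1.3 for vitellogenin genes. The direction also turned for germ granule and germline genes with a 150 bp window (1.65), and for RNA polymerase and general transcription factor genes in the 50% of IDR peaks with the highest signal (0.80).

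The strongest protein-coding sites with no listed non-coding RNA gene within 500 bp were syp-3, a synaptonemal complex component (I, 8663045 to 8664445, 106 bp upstream, signal 4214, rank 78), eelo-2 (224 bp upstream, rank 131), ntl-11 (117 bp upstream, rank 141), rpl-29, Y71G12B.23 (264 bp downstream, rank 188) and tsr-2 (178 bp upstream, rank 189). In all, 58.9% of IDR summits were within 300 bp of an annotated 5' end, against 37.2% of the other candidates. Of the IDR summits farther away, 20.2% of the total were intergenic (15.8% of other candidates), 16.2% were intronic (25.9%) and 4.62% were exonic (21.1%). The deposited lists were derived with a control whose kind is not given in the sources used here, and recovery by the anti-GFP antibody regardless of SNPC-4 was not tested.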

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

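Leaving out the mitochondrial genome and using RefSeq symbols were chosen after the data were examined. Of 250 values under alternatives, 233 kept their direction and, where a test was run, their side of the threshold, where a change of sign between 2 values short of the threshold counted as kept. Odds ratios at SL RNA (19 to 114), snRNA (31.0 to 136), tRNA (15.3 to 51), snoRNA (5.63 to 12.8), miRNA (2.03 to 2.86), other non-coding RNA (2.30 to 4.94) and protein-coding genes (1.48 to 1.84) passed the threshold under every alternative run, as did the rotation and random placement, which give ratios of counts. At piRNA genes the odds ratio reversed to 0.448 in the stronger 50% of the peaks and passed the threshold with merged regions (1.24) and random placement (2.22-fold); leaving out each replicate gave 0.953 to 1.17, past the threshold without replicate 1. At rRNA genes, with 5 peaks, the stronger 50% gave 4.34, past the threshold, and leaving out each replicate 3.01 to 6.51, against 1.63 without the mitochondrial genome, 1.35 with 150 bp and 1.32-fold with rotation. Rotation ended the calls for the domains (1.13-fold, the size of the ratio of counts without it) and for the motif outside them (0.701-fold), as did, for the latter, a distance of 200 bp (0.880). The reversed control sequence gave 0.635 there, about the motif's own value, and did not pass. In the domains the motif reversed in the stronger 50% (0.271). Ribosomal protein genes were no longer past the threshold with 150 bp (2.20), against 22.3 with 500 bp and 16.6 with merged regions, and histone genes passed in the stronger 50% (4.85). IDR peaks in both replicate lists were 93.5% with summits within 100 bp and 79.0% with overlap of 50% of each, and in the strongest regions of both 69.8% and 59.1%. Apart from rotation, which keeps the clustering of labels, the cause was not tested. The neuronal list, with no candidate, gave no odds ratio. No paired analysis was possible because the labels give 1 group. Depth is unknown, so its limit on weak peaks was not assessed.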

Other observations

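The tests of tRNA genes by chromosome and isotype, of the piRNA domains by rank and of TGTCGG in the domains were chosen only after the result was seen, TGTCGG itself came from the 6-base counts in these data, and the 3 patterns weighed here were found in the same data. Within the SL RNA genes as named by RefSeq, all 19 of the sls-2 genes, the pseudogene sls-2.19 included, had an IDR peak within 300 bp of the 5' end, and 0 of 12 sls-1 genes did. The sls-1 genes lie in a repeated array on chromosome V, and 3 of them had a candidate region; whether reads can be placed uniquely there was not tested. All 12 smy genes, annotated as snRNA or snoRNA genes on chromosomes IV and V, had an IDR peak.

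Chromosome X stood out for tRNA genes. Of 653 IDR peaks on X, 27.6% lay at a tRNA 5' end, against 5.17% on the other chromosomes. An IDR peak was found at 186 of 276 tRNA genes on X (67.4%) and at 193 of 336 on the autosomes (57.4%; odds ratio 1.53, 95% interval 1.1 to 2.13). Both this and the next interval take genes or regions as independent, which clustered ones are not. With tRNA regions left out, 18.2% of X candidates and 14.2% of the others passed IDR (odds ratio 1.35, 1.22 to 1.50). Of 20 tRNA isotypes none passed Fisher's exact test after adjustment; tRNA-Asp (23 of 27) and tRNA-Val (25 of 31) were highest, and tRNA-Arg (20 of 44, adjusted p = 0.24 as for those 2) and tRNA-Phe (6 of 14, adjusted p = 0.55) lowest. On the mitochondrial genome 15 of 17 candidates passed IDR.

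Among the 300 strongest peaks, 78 had no annotated 5' end within 300 bp (40 intergenic, 29 intronic, 9 exonic). Of the 78, 24 lay in the piRNA domains and 5 on the mitochondrial genome, the latter all exonic and without TGTCGG. The values argue against shoulders of stronger neighbours, since 6.41% of the 78 (exact 95% interval 2.11 to 14.3) had a higher summit within 1000 bp. TGTCGG, found upstream of snRNA, SL RNA and snoRNA genes, lay within 100 bp of 59.0% of these summits and of 6.82% of other candidates without a 5' end (odds ratio 19.6, 12.5 to 31.0), against 2.17 (0.995 to 4.74) for GGCTGT. Repeats stay open as a source: soft-masked bases were 17.24 percentage points (9.11 to 25.8) more frequent than at the peaks of the same ranks with a 5' end (39.5% against 22.2%; other candidates without a 5' end 35.3%), but in sequence under 20% masked the element was still enriched at 14 of 29 peaks (odds ratio 9.46, 4.54 to 19.7). As a hypothesis, part of these sites may be unannotated promoters of the snRNA type; recovery by the antibody regardless of SNPC-4 was not tested.

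At tRNA genes the summits lay mostly from the gene start to some way downstream of it (quartiles -14 and 64 bp), and not upstream as at snRNA genes. The 51 tRNA peaks with a signal of 1000 or more had a median offset of 7 bp (bootstrap 95% interval -14 to 10). This argues against weak, imprecise peaks alone, but these 51 were not cleared of neighbouring genes, and the strongest lay nearer to the SL RNA gene sls-2.9. Neighbouring small RNA genes alone do not account for the position either, since 115 peaks of any signal with none within 500 bp had a median of 23 bp (10 to 37). Strong peaks without such neighbours were not tested, so both explanations together stay open. TGTCGG was not enriched at tRNA summits (odds ratio 0.968, 0.638 to 1.47), whereas the control GGCTGT was (1.64, 1.08 to 2.49). A candidate explanation is another mode of recruitment at tRNA genes, such as contact with the RNA polymerase III machinery, which was not tested; enrichment of highly transcribed genes by the precipitation itself was not tested either.

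The high peak density in the piRNA domains was weighed against raised background. Of 1406 domain summits 25.6% lay within 50 bp of a piRNA 5' end, above 1000 random placements (mean 16.8%, highest 19.8%) and placements matched on exon, intron and intergenic location (mean 18.2%, highest 21.4%). Of the 907 peaks ranked after 2000, 36.8% lay there, against a mean of 16.9% and a highest of 20.7% in 1000 random placements not matched on location. These values argue against background spread evenly over both domains for those peaks. The placements were not matched on domain: the left domain spans 2.5 Mb and held 242 IDR peaks, the right one 3.7 Mb and 1164. Annotated piRNA genes reached 978 per 500 kb bin in the left domain and 1915 in the right one. Part of the excess can therefore come from the domain in which the peaks lay, and background spread evenly within each domain was not tested. Candidates outside the IDR list also exceeded the placements (24.7%), but their share fell with rank. It was 33.3% at ranks 4676 to 10000, 23.5% at 10001 to 20000 and 17.8% at 20001 to 30000. The placements assume even background, so they cannot tell binding at piRNA 5' ends from background raised near them. Peaks ranked 1 to 2000 lay below every random placement (5.21% of 499, lowest 11.8%), which argues against piRNA 5' ends as their site. These may in part be sites of the snRNA type, as a hypothesis, since TGTCGG was at 26.9% of them against 5.61% of other domain candidates, with SL RNA, snRNA and snoRNA genes left out (odds ratio 6.19, 4.93 to 7.77; GGCTGT 2.35, 1.60 to 3.46).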
